A study of Bos taurus with 12 samples.

How the data were processed

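The measured quantity was the abundance of transcripts in bovine ovarian follicles, read on Affymetrix bovine arrays of 1 colour with biotin-labelled total RNA, per the labels. Granulosa cells, the epithelial cells that line the inside of the follicle, and theca cells, the vascular steroid-producing layer outside it, were taken from small follicles (up to 5 mm), medium follicles (5 to 10 mm) and large follicles (over 10 mm). That gave 6 groups of 2 arrays and 12 arrays in all. Ovaries came from cycling heifers in the follicular stage, judged by the lack of a corpus luteum, and reached the laboratory on ice, per the labels' protocols. The extract protocol in the labels states that cells of 20 to 40 follicles of 1 size were pooled for each RNA sample, whereas the design text speaks of 20 to 40 ovaries from 6 to 10 animals. The labels call the replicates biological and separate, but do not say whether pools shared animals. The p-values therefore measure the spread between pools, and pooling hides the spread between animals.

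Groups were taken from the sample titles. The description field names theca cells for all 12 samples, while title and source name give granulosa cells for 6 of them. The titles were used, and the levels of cell type markers given with the results bear on this choice. All 12 columns of the table matched a sample by its own identifier, and 0 columns stayed unmapped.

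The deposited values were array signal intensities on a linear scale, 1 per probe set and array. The software that made them, its version and its settings are not given in the sources used here, and detection calls were not used here. The authors had scaled them: the 2% trimmed mean over the 24128 probe sets was 125.03 to 125.04 on every array. The signal medians ran from 33.6 to 48.7. The number of arrays, 2 per group, limits the precision, and an exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333. Tests were therefore made with limma, which shares information on the spread across probe sets.

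Of the 24128 probe sets, 112 were hybridisation and labelling controls and stayed out of the tests. Among the other 24016, 13292 had 1 gene symbol in the platform annotation, 86 had several symbols and were not named, and 10638 were unnamed here. The symbols stood for 9155 genes. For 13263 of the named probe sets the Entrez identifier was found in the gene table of assembly ARS-UCD2.0, which was used for names only, and 0 symbols changed.

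Signals were turned into log2(signal + 16). This keeps low signals from giving large folds, so a fold of a dim gene is understated, and every fold below is on that scale. The deposited scale was kept because the array medians spanned 0.383 on the log2 scale, below the limit of 0.5 set beforehand. A probe set was tested if its mean in at least 1 group exceeded the 40th percentile of all values, a signal of 22.5, which left 17236 probe sets for 7893 genes. A limma model (version 3.58.1, in R 4.3.3) with a mean per group was fitted over all 12 arrays, which leaves 6 residual degrees of freedom. Its moderated test without trend had 7.92 prior degrees of freedom and a prior SD of 0.376. There were 13 contrasts: 3 pairs of sizes in each cell type, granulosa against theca over all sizes and within each size, and the difference between the cell types in each size change. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Standard errors are those of the model. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

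There were 26 gene lists of cell types and pathways, with 617 entries, of which 474 had a probe set. For a gene with several probe sets the one with the highest mean stood for it in a list. Lists with at least 5 tested genes were tested with camera of limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes, and adjusted over the 325 list tests together. Of these, 105 passed. With the correlation estimated from the data 4 passed, namely the theca markers in the 4 granulosa against theca contrasts. Groups of 2 arrays leave that estimate imprecise.

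The genes named follow a rule. In each size contrast these are 13 key genes of follicle function (FSHR, LHCGR, CYP19A1, CYP17A1, CYP11A1, STAR, HSD3B1, HSD17B1, INHA, INHBA, FST, AMH and INSL3). In every contrast they include the called list members with the largest changes, up to 4 per list, and the 6 largest rises and 6 largest falls among called genes with 1 symbol and arrays that did not overlap between the groups (within every size for the contrast over all sizes), with at most about 30 genes per contrast. Further list members and probe sets without a symbol were named after their values had been seen. Groups, contrasts, tests, filter, lists, naming rule and the alternatives were fixed before the data were examined, apart from 3 alternatives and those tests that the closing parts name as added later.

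The procedure was tested on simulated data for the large against small granulosa contrast over 17236 probe sets. Values were drawn independently from normal distributions, with the same spread in all groups for a probe set. It called 4 of 67 probe sets given a log2 change of 1 (5.97%), 56 of 67 at a change of 2 (83.6%) and 66 of 66 at 3 (100%). There were 131 calls, 5 of them on unchanged probe sets and 0 with the wrong sign. A cell cycle list shifted by 0.5 was called, and 1 of the other lists, 25 being tested, was called without a shift. In the real arrays the SD of the difference between replicates ran from 0.427 (medium theca) to 0.79 (small theca), and genes may vary together. The simulated rates therefore need not hold for them.

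The alternatives were log2(signal + 1) and log2(signal + 64), no filter, a filter at the 60th percentile, quantile normalization, a trended prior, only the arrays compared, the replicate number as a block, each array left out in turn, the estimated list correlation and every other probe set of a named gene. When an array is left out, the lone array of its group is assumed to vary like those of the other groups. Genome positions and sequences were not analysed here.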

Results

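Transcript signals of granulosa and theca cells from bovine antral follicles of 3 sizes were compared on 12 arrays, 2 biological replicates for each cell type and size, over 17236 tested probe sets. The questions were how each cell layer changes as follicles grow and how the layers differ. Changes are log2 changes ± standard error of the limma model, with n = 2 arrays per group, and adjusted p-values come from limma. The replicates correlated with Spearman coefficients of 0.926 for small, 0.928 for medium and 0.896 for large granulosa, and 0.867 for small, 0.948 for medium and 0.943 for large theca. Between 0.327% and 0.638% of values were identical within a replicate pair, so no array was a copy of its replicate.

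A pair of arrays stood apart from the rest. On theca small replicate 1 the GAPDH control transcript gave 8.36 times the signal at its 3' end over its 5' end, against 0.984 to 1.30 on the other arrays, a sign of shortened RNA. Granulosa large replicate 1 had the highest median signal, 48.7 against 33.6 to 39.1 elsewhere, and an actin 3' over 5' ratio of 21.0. It also held the haemoglobin transcript HBB at 9.22 (log2), against 4.58 to 5.66 in the small and medium granulosa arrays and 6.05 in granulosa large replicate 2. Counts without both arrays are given beside the comparisons they enter, as an alternative chosen after seeing the data.

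**Figure D1:**
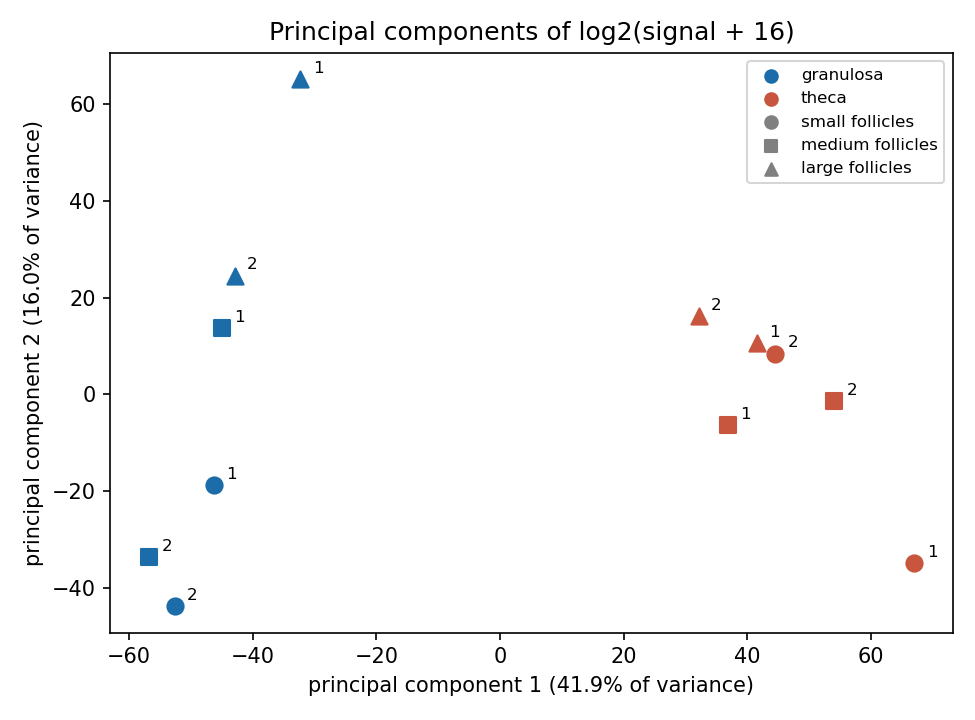
Position of the 12 arrays on the first and second principal components of log2(signal + 16), which hold 41.87% and 16.01% of the variance; each point is 1 array, coloured by cell type and shaped by follicle size. The 6 granulosa arrays lie between -56.8 and -32.3 on the first component and the 6 theca arrays between 32.1 and 67.0, with granulosa large replicate 1 at 65.2 and theca small replicate 1 at -34.9 on the second.

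Granulosa and theca were compared over all sizes to describe the layers and to check the labels. Theca cells held far more of CYP17A1, the enzyme that makes androgens, with a granulosa minus theca change of -5.42 ± 0.33 (42.8-fold, adjusted p = 9.7e-08). INSL3, a peptide hormone of theca cells, differed by -3.89 ± 0.27 (adjusted p = 3.38e-07). Granulosa cells held more of the epithelial keratin KRT18 (3.77 ± 0.23, 13.7-fold, adjusted p = 9.19e-08), of CRABP2, which binds retinoic acid (3.77 ± 0.35, adjusted p = 4.09e-06), and of IHH, a ligand of the hedgehog pathway (3.20 ± 0.39, adjusted p = 6.26e-05). SPP1, the secreted protein osteopontin, differed by 3.40 ± 0.42, the integrin subunit ITGAV by 3.03 ± 0.58 and ANKRD1 by 2.98 ± 0.51, all called as higher in granulosa. The samples whose titles say granulosa thus carried granulosa markers, while their description field names theca. In all, 4273 probe sets differed, 2337 higher in granulosa and 1936 higher in theca, and 1749 of them at least 2-fold. After quantile normalization 2013 were higher in granulosa and 2081 in theca. The count was 2648 without theca medium replicate 2 and 4291 without both arrays that stand apart.

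Of 10 theca markers, 7 were lower in granulosa over all probe sets and 8 when adjusted over the list alone, with a median of -2.92 (adjusted p = 5.69e-10, and adjusted p = 0.0473 with an estimated correlation). APOD, a lipid carrier, differed by -4.26, the transcription factor TCF21 by -3.63 and the nuclear receptor NR2F2 by -3.27. STAR, which carries cholesterol into mitochondria, was on that list too but gave -0.18 with an adjusted p of 0.757. Of 16 granulosa markers, 13 were higher in granulosa and 16 when adjusted over the list alone, with a median of 1.47 (adjusted p = 6e-09, and adjusted p = 0.283 with an estimated correlation). Among them were the FSH receptor FSHR (1.86), anti-Mullerian hormone AMH (1.56), the inhibin subunit INHBA (1.55) and aromatase, CYP19A1 (1.25, adjusted p = 0.0227). The receptor for LH, LHCGR, was lower in granulosa (-1.13). Among 17 genes of steroidogenesis 6 were higher and 4 lower, and the list did not pass (median -0.13, adjusted p = 0.833).

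Genes of the theca wall other than its steroid cells were lower in granulosa too. Of 14 fibroblast and stroma markers 11 were lower in granulosa and 1 higher, with a median of -2.26 (adjusted p = 9.66e-09, and adjusted p = 0.274 with an estimated correlation). OGN (-5.36), DPT (-4.74), ASPN (-4.09) and the collagen COL1A1 (-4.12) were among them. Of 14 endothelial markers 11 were lower, with a median of -1.78 (adjusted p = 5.69e-10, and adjusted p = 0.283 with an estimated correlation), such as the vessel sialomucin EMCN (-2.87). The contractile genes of pericytes and smooth muscle were lower for 8 of 12 members (adjusted p = 6.98e-06, and adjusted p = 0.265 with an estimated correlation), with RGS5 at -3.60, ACTA2 at -3.53, MYLK at -3.37 and MYH11 at -2.71. Of 33 extracellular matrix genes 21 were lower and 3 higher, with a median of -1.74 (adjusted p = 5.16e-10, and adjusted p = 0.346 with an estimated correlation). The elastic fibre gene FBLN5 (-4.84) and the basement membrane gene NID1 (-4.61) led this group. MGP, an inhibitor of calcification, gave -5.22 on its brightest probe set, but 1 of its 2 other probe sets gave 0.22. The retinal dehydrogenase ALDH1A1 (-4.96) and ADAMDEC1 (-4.86) were also lower in granulosa, as was SPARCL1, by 32.0-fold.

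The IGF binding proteins split between the layers. IGFBP3 (-3.05), IGFBP4 (-2.95), IGFBP6 (-3.66) and the growth factor IGF2 (-2.98) were lower in granulosa, whereas IGFBP5 (2.86), IGF1 (1.69) and the insulin receptor INSR (1.74) were higher. One other probe set of IGF2 gave 0.38. Of the 13 IGF system genes 5 were higher and 4 lower, and median (0.40), mean (-0.25) and test (down, adjusted p = 0.885) differed in sign. Granulosa cells held more of 15 of 24 hypoxia and glycolysis genes and less of 1, with a median of 0.78 (adjusted p = 1.25e-05, and adjusted p = 0.384 with an estimated correlation). These included the angiogenic factor VEGFA (2.58) and the glucose transporters SLC2A3 (2.30) and SLC2A1 (2.07). Cell cycle genes were higher for 11 of 29 members, 16 when adjusted over the list alone (median 0.58, adjusted p = 1.41e-05, and adjusted p = 0.59 with an estimated correlation), for example UBE2C (1.70) and PLK1 (1.24). Immediate early and heat shock genes, which respond within an hour to handling, were higher for 9 of 20 members and lower for 1 (median 0.41, adjusted p = 0.00575, and adjusted p = 0.469 with an estimated correlation), among them ATF3 (1.85) and ZFP36 (1.87).

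The remaining lists did not pass between the layers over all sizes, which does not show that they were level. With higher and lower members called, these were TGF-beta and BMP genes (8 and 4 of 25, adjusted p = 0.273), matrix proteases and inhibitors (5 and 5 of 22, adjusted p = 0.775), antioxidant genes (6 and 4 of 24, adjusted p = 0.571) and immune markers (3 and 3 of 18, adjusted p = 0.823). LH surge genes (3 and 1 of 14, adjusted p = 0.137), interferon genes (0 and 3 of 13, adjusted p = 0.206), cholesterol genes (1 and 2 of 17, adjusted p = 0.645), WNT and NOTCH genes (0 and 5 of 17, adjusted p = 0.071) and red blood cell genes (0 and 0 of 5, adjusted p = 0.432) did not either. The same held for 5 lists that were not called in any of the 13 contrasts. These were apoptosis (1 and 3 of 15), endoplasmic reticulum stress (3 and 0 of 17), cell cycle inhibitors (1 and 0 of 9), hormone receptors and cAMP signalling (2 and 3 of 18, where the median of 0.13 and the mean of -0.10 differed in sign) and other growth factors (2 and 5 of 25). Of the oocyte markers only 4 were tested, too few for a list test. MOS was higher in granulosa (0.82, adjusted p = 0.0305) and ZP2 lower (-0.71, adjusted p = 0.0129), at a list median of 0.64. A mean over sizes can hide opposite shifts. Immune markers were lower in granulosa in small follicles and higher in large ones, as given below.

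Within sizes, the layers differed in 1575 probe sets in small follicles (700 higher in granulosa), 1034 in medium follicles (308) and 760 in large follicles (348). Across the 3 sizes, 47 probe sets were higher in granulosa each time and 251 higher in theca. The small and large comparisons, which share no array, had 77 probe sets higher in granulosa in common against 14.1 for independent lists, and 275 higher in theca against 20.9. Both comparisons took the spread of a probe set from the same fit. The lists were therefore not independent, and these values are not chance levels. CYP17A1 was lower in granulosa by -5.94 ± 0.57 in small, -5.29 ± 0.57 in medium and -5.03 ± 0.57 in large follicles, and KRT18 higher by 4.33, 3.45 and 3.53 (standard error 0.40 each). The theca markers kept their shift in each size, with medians of -3.16, -3.38 and -2.89 (adjusted p = 0.0489, 0.0473 and 0.0473 with an estimated correlation). In small follicles CRABP2 (4.48), IGFBP5 (3.55) and NR5A2 (2.90), a nuclear receptor that drives steroid enzymes, were higher in granulosa, and DPT (-5.83), EGFLAM (-5.52) and COL15A1 (-5.04) lower. The count fell to 501 without granulosa small replicate 2, 561 without theca small replicate 1, 713 without granulosa small replicate 1 and 797 without both arrays that stand apart. It rose to 2232 without theca small replicate 2, where the balance turned to 1271 higher and 961 lower in granulosa. The chemokine XCL1 (4.52), MAP1LC3C (3.63), ITGAV (3.60) and LOC514170 (3.60) were not called without theca small replicate 1, with adjusted p-values of 0.255, 0.201, 0.291 and 0.102 in turn, nor without granulosa small replicate 2.

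In medium follicles CRABP2 (3.74), CDH2, the N-cadherin of granulosa junctions (3.12), SPP1 (3.61) and ANKRD1 (3.80) were higher in granulosa, and OGN (-5.53), RARRES1 (-5.11), CXCL14 (-5.03) and the BMP target ID1 (-3.16) lower. The 14 endothelial markers were all lower, 12 of them called, at a median of -2.38 (adjusted p = 1.01e-15, and adjusted p = 0.265 with an estimated correlation). The count was 360 (25 higher in granulosa) without theca medium replicate 2, 426 without granulosa medium replicate 2 and 502 without theca medium replicate 1. It rose to 1600 without both arrays that stand apart. Without theca medium replicate 2 the calls of ANKRD1 (adjusted p = 0.302), CDH2 (adjusted p = 0.167) and SPP1 (adjusted p = 0.132) were lost, as they were without granulosa medium replicate 1.

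In large follicles the genes highest in granulosa included markers of myeloid blood cells, S100A12 (4.17 ± 0.55, adjusted p = 0.000825), S100A8 (3.77 ± 0.49) and FCN1 (3.51 ± 0.51), beside KRT18. The 18 immune markers were all higher in large granulosa, 5 of them called and 14 when adjusted over the list alone, at a median of 1.52 (adjusted p = 2.17e-09, and adjusted p = 0.464 with an estimated correlation). In small follicles the same list was lower in granulosa, at a median of -1.03 with 4 of 18 called (adjusted p = 0.00124, and adjusted p = 0.657 with an estimated correlation). SCG2 (-5.81), ASPN (-5.08), OGN (-5.04) and MYH11 (-4.32) were lower in large granulosa. Endothelial markers differed by a median of -0.44 (adjusted p = 0.0348, and adjusted p = 0.657 with an estimated correlation; adjusted p = 0.577 without theca large replicate 1, and lost without granulosa large replicate 2 too, or with log2(signal + 1), 0.0743, or log2(signal + 64), 0.0629). The count was 199 without theca large replicate 1, 233 without theca large replicate 2, 284 without granulosa large replicate 1 and 516 without both arrays that stand apart. HSD17B1, which turns oestrone into oestradiol (2.86), VEGFA (2.73) and MMP19 (2.99) lost their calls without granulosa large replicate 1 or theca large replicate 2, and the first and second of them without theca large replicate 1 (highest adjusted p 0.208, 0.112 and 0.204). After quantile normalization 33.9% of the calls were higher in granulosa, against 45.8% on the deposited scale. The balance depended on single arrays, with 64.9% higher in granulosa without granulosa large replicate 2, 25% without granulosa large replicate 1 and 16.3% without theca large replicate 2.

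The comparison of large with small follicles in granulosa asked what changes as a follicle matures. CYP19A1, the aromatase that makes oestradiol, rose 17.8-fold (4.15 ± 0.63, adjusted p = 0.00587), from signals of 113 and 126 to 3134 and 1821. The chemokine CCL5 rose 22.7-fold (4.50 ± 0.44, adjusted p = 0.00116), from 2.4 and 2.9 to 557 and 297. The macrophage genes TIMD4 (4.26) and CD5L (4.23), the ribonuclease genes BRB (4.18) and RNASE6 (4.14), and TNFAIP6, which crosslinks hyaluronan in the ovulatory matrix (2.95 ± 0.60, 7.73-fold, adjusted p = 0.0192), rose too. LTF, the iron-binding protein lactoferrin, fell 9.76-fold (-3.29 ± 0.46, adjusted p = 0.00419), and RPRM, which halts the cell cycle (-2.93), MYH11 (-2.83), MEST (-2.62), RASL11B (-2.44) and DDO (-2.42) fell. In all 382 probe sets changed, 313 up and 69 down, for 205 and 36 named genes. With limma, 0 were called without granulosa large replicate 1, where 1780 had an unadjusted p under 0.05, so that no gene named here kept its call. There were 2 calls without granulosa small replicate 1, 61 without granulosa small replicate 2, 635 without granulosa large replicate 2 and 58 without both arrays that stand apart. With log2(signal + 1) the count was 227, and RPRM, MEST and TNFAIP6 were not among the calls.

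The other key genes did not pass in large against small granulosa. LHCGR gave 1.35 ± 0.36 (adjusted p = 0.0716) and INHBA 1.79 ± 0.50 (adjusted p = 0.085, and 0.0385 in a fit of granulosa arrays alone). AMH gave -1.70, INHA 0.93, FSHR -0.66, CYP17A1 1.39, CYP11A1 0.53, HSD17B1 -0.59, STAR -0.36, HSD3B1 0.23, INSL3 -0.16 and FST -0.06, all with an adjusted p of at least 0.163. The list of 16 granulosa markers held 1 gene up and 1 down, with a median of -0.33, a mean of 0.02 and a test pointing down (adjusted p = 0.85).

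Immune markers rose as a group in large granulosa. All 18 were called up, with a median of 3.24 (adjusted p = 3.03e-27, and adjusted p = 0.274 with an estimated correlation). They included the complement genes C1QA (3.94) and C1QC (3.68), S100A8 (3.80) and the macrophage protein CD68 (3.69). Without granulosa large replicate 1, an array that stood apart, the list kept a median of 2.52 but limma called 0 of the 18, and 1780 of all probe sets had an unadjusted p under 0.05. Without granulosa small replicate 1 only 2 of all probe sets were called. Of 22 matrix proteases and inhibitors 5 rose, 7 when adjusted over the list alone (median 0.58, adjusted p = 0.000404, and adjusted p = 0.464 with an estimated correlation). They were CTSS, a protease of antigen-presenting cells (3.92), MMP19 (2.87), the plasminogen activator PLAU (2.84), CTSK (1.81) and MMP9 (1.67). At least CTSS and MMP9 are also made by leukocytes, and the cell source of the 5 rises was not tested. The 13 interferon response genes all moved up, 0 called over all probe sets by limma and 9 when adjusted over the list alone (median 1.30, adjusted p = 1.28e-06, and adjusted p = 0.459 with an estimated correlation). Endothelial markers shifted up by a median of 0.63 (adjusted p = 0.00774, and adjusted p = 0.606 with an estimated correlation), with an adjusted p of 0.112 without granulosa large replicate 1, and were not called without granulosa small replicate 1 either. Hypoxia and glycolysis genes shifted by 0.44 (adjusted p = 0.0152, and adjusted p = 0.59 with an estimated correlation), with an adjusted p of 0.396 without granulosa small replicate 1 and no call without granulosa large replicate 2. HBB gave 2.82 with an adjusted p of 0.0628, and the red blood cell list a median of 0.68 (adjusted p = 0.096). The LH surge list had a median of -0.15 and a mean of 0.27, and matrix genes a median of -0.03 and a mean of 0.25, neither called.

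**Figure D2:**
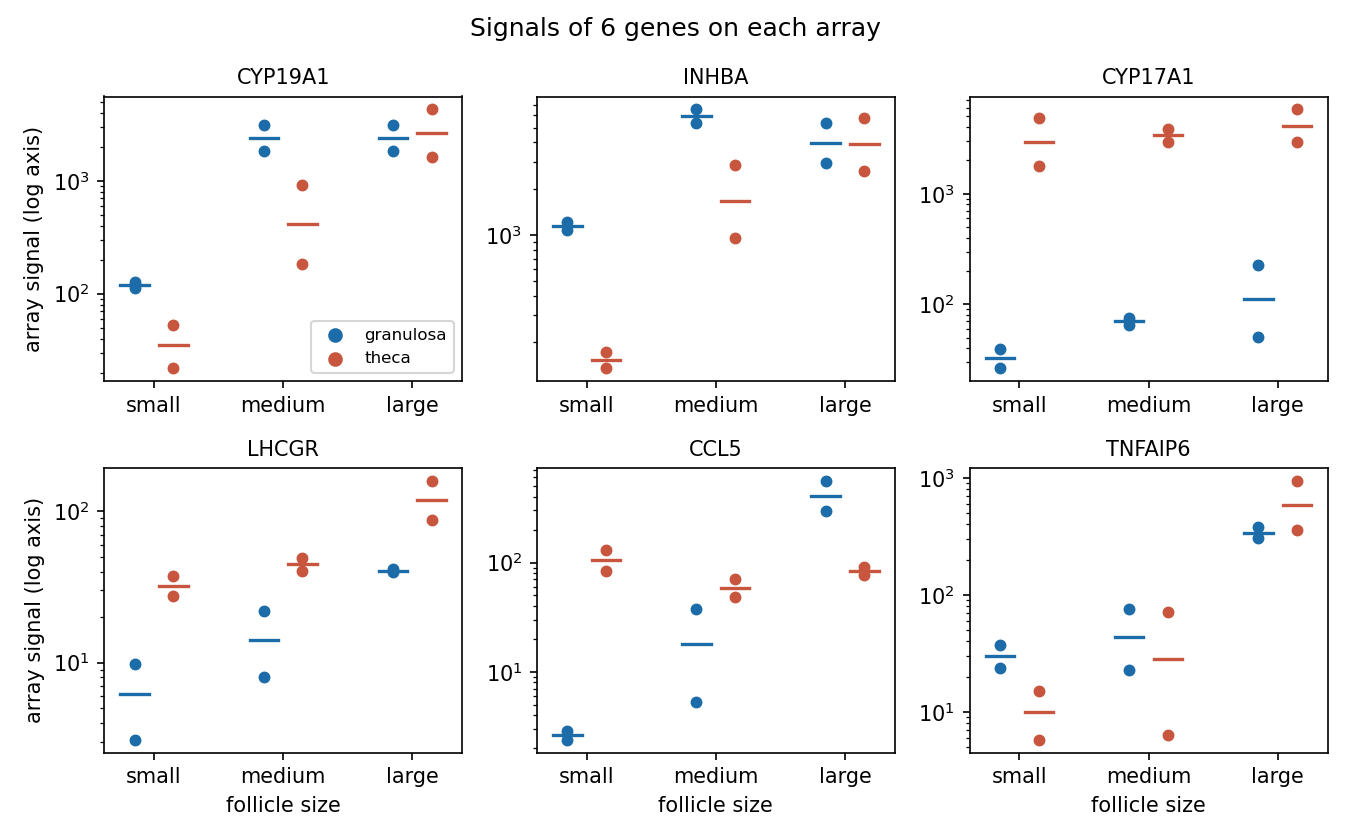
Signals of CYP19A1, INHBA, CYP17A1, LHCGR, CCL5 and TNFAIP6 on a logarithmic axis for granulosa and theca of small, medium and large follicles; each point is 1 array and each bar the mean of log2(signal + 16) turned back into signal. CCL5 reached 557 and 297 in large granulosa against 2.4 and 2.9 in small granulosa, and CYP19A1 reached 1633 and 4279 in large theca against 21.9 and 52.8 in small theca.

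Between medium and small granulosa CYP19A1 gave 4.14 ± 0.63 (17.7-fold), with signals of 3114 and 1820 in medium follicles, but it did not pass (adjusted p = 0.0621). It passed in a fit of granulosa arrays alone (adjusted p = 0.00239). INHBA gave 2.36 ± 0.50 (adjusted p = 0.255), KRT18 -2.38 (adjusted p = 0.0788) and AMH -1.04. The 1 probe set called had no gene name here and fell by 2.55 ± 0.34 (adjusted p = 0.0469). Its call was lost without either medium theca array, where a rising probe set was called instead. The limma count was 0 without any 1 of the granulosa arrays or of the large theca arrays, 8 without either small theca array, and 12 without both arrays that stand apart. With limma, 581 probe sets had an unadjusted p under 0.05, fewer than the 862 of chance. Among the lists, 27 of 29 cell cycle genes were higher in medium granulosa (median 0.51, adjusted p = 1.8e-07, and adjusted p = 0.532 with an estimated correlation), with an adjusted p of 0.0891 without granulosa small replicate 1. Of 20 immediate early and heat shock genes 15 were lower, 4 called when adjusted over the list alone (median -0.45, adjusted p = 1.39e-06, and adjusted p = 0.283 with an estimated correlation), led by FOS (-1.90) and NR4A1 (-1.49).

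Smaller list shifts in medium against small granulosa were each lost when 1 array was left out. Immune markers had a median of 0.47 (adjusted p = 0.000309, and adjusted p = 0.657 with an estimated correlation; 0.606 without granulosa medium replicate 1). Interferon genes had 0.30 (adjusted p = 0.0112, and adjusted p = 0.657 with an estimated correlation; 0.425 without granulosa medium replicate 1). Cholesterol genes had 0.31 (adjusted p = 0.00346, and adjusted p = 0.657 with an estimated correlation; 0.92 without granulosa medium replicate 2). LH surge genes had -0.38 (adjusted p = 0.00353, and adjusted p = 0.346 with an estimated correlation; 0.161 without granulosa small replicate 1). For IGF system genes the median was -0.31 (adjusted p = 0.0202, and adjusted p = 0.283 with an estimated correlation; 0.117 without granulosa small replicate 1). Steroidogenesis genes gave 0.15 (adjusted p = 0.0371, and adjusted p = 0.346 with an estimated correlation; 0.358 without granulosa small replicate 1), and TGF-beta genes 0.27 (adjusted p = 0.0381, and adjusted p = 0.548 with an estimated correlation; 0.273 without granulosa medium replicate 1). All of these calls were lost without granulosa small replicate 1. Those of the IGF system and TGF-beta lists were lost without any of the 4 small and medium granulosa arrays, that of steroidogenesis without either medium array, and that of LH surge genes without granulosa medium replicate 2. With log2(signal + 1) or a filter at the 60th percentile the steroidogenesis (adjusted p = 0.0615 and 0.0538) and TGF-beta (0.0687 and 0.113) calls were lost. The TGF-beta call was also lost with log2(signal + 64) (0.0555), and without a filter that of the IGF system (0.0567). Immune markers stood at a median log2 signal of 6.80 on granulosa medium replicate 1 but 5.75 on replicate 2, against 5.87 and 5.75 in small granulosa. Cholesterol genes stood at 8.83 on granulosa medium replicate 2. On replicate 1 they stood at 8.11, between the 7.75 and 8.23 of small granulosa. Each of these rises thus rested on 1 medium array.

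From medium to large follicles granulosa again gained immune genes. CCL5 rose 12.5-fold (3.64 ± 0.44, adjusted p = 0.00755), the immunoglobulin chain IGHM 10.9-fold (3.44 ± 0.40, adjusted p = 0.00755) and the complement gene C1QB 11.8-fold (3.56 ± 0.57, adjusted p = 0.0173). ACP5 (3.46), UBD (3.41), ARHGDIB (3.41), S100A8 (3.29), the antigen-presenting BOLA-DRA (3.28), C1QC (3.23), the chemokine receptor CXCR4 (2.75), PLAU (2.52) and the matrix protein TNC (2.28) rose as well. SPON1 (-2.49), GRAMD4 (-1.79) and METTL22 (-1.69) fell, and CYP19A1 was level at 0.01 ± 0.63. A total of 117 probe sets changed, 112 up and 5 down. With limma, 0 were called without granulosa large replicate 1, without granulosa medium replicate 2 or without both arrays that stand apart, where 1343, 1021 and 1717 in turn had an unadjusted p under 0.05, against 1997 over all arrays. The count was 43 without either small granulosa array, 45 without either medium theca array and 487 without granulosa large replicate 2, and 5 with log2(signal + 1), under which none of the rises and falls named here passed.

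All 18 immune markers were higher in large than in medium granulosa, 13 of them called and 18 when adjusted over the list alone (median 2.61, adjusted p = 2.86e-26, and adjusted p = 0.274 with an estimated correlation). None of the 13 calls was left without granulosa large replicate 1 or without granulosa medium replicate 2. All 14 endothelial markers were higher, 0 called by limma and 2 when adjusted over the list alone (median 0.70, adjusted p = 0.00021, and adjusted p = 0.494 with an estimated correlation). Of the matrix proteases PLAU alone was called, and 7 members when adjusted over the list alone (median 0.66, adjusted p = 0.000116, and adjusted p = 0.459 with an estimated correlation; 0.0903 without granulosa medium replicate 2). All 13 interferon genes were higher (median 0.79, adjusted p = 0.000644, and adjusted p = 0.569 with an estimated correlation; 0.107 without granulosa large replicate 1). Of 29 cell cycle genes 25 were lower (median -0.33, adjusted p = 0.00225, and adjusted p = 0.684 with an estimated correlation; 0.0974 without granulosa large replicate 1). LH surge genes shifted up (median 0.45, adjusted p = 0.00462, and adjusted p = 0.354 with an estimated correlation; 0.0664 without granulosa large replicate 1), as did immediate early genes (median 0.35, adjusted p = 0.0162, and adjusted p = 0.525 with an estimated correlation; 0.149 without granulosa medium replicate 2, and lost without granulosa large replicate 2). Beside these, 5 of 5 red blood cell genes were higher (median 0.85, adjusted p = 0.0216, and adjusted p = 0.603 with an estimated correlation; 0.671 without granulosa large replicate 1, and lost without granulosa medium replicate 2).

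In theca, the comparison of large with small follicles gave few but large changes. CYP19A1 rose 52.1-fold (5.70 ± 0.63, adjusted p = 0.00203), from signals of 21.9 and 52.8 to 1633 and 4279. INHBA, which forms activin and inhibin, rose 23.2-fold (4.54 ± 0.50, adjusted p = 0.00203), TNFAIP6 23.1-fold (4.53 ± 0.60, adjusted p = 0.00907) and the apolipoprotein APOA2 12.4-fold (3.64 ± 0.47, adjusted p = 0.00906). LOC767968, whose synonym is BEX2, rose by 2.70 ± 0.38 (adjusted p = 0.0134), and a probe set without a gene name here rose 27.8-fold (adjusted p = 0.00203). These were the 6 probe sets called, all up, and with limma 0 were called without theca large replicate 2, where CYP19A1 gave 5.01 (adjusted p = 0.0618) and 817 had an unadjusted p under 0.05, and 607 without theca small replicate 2. TNFAIP6 and APOA2 also lost their calls without theca small replicate 1, and LOC767968 without theca large replicate 1, and 1 call was left without both arrays that stand apart. Another probe set of CYP19A1 gave 2.63 (adjusted p = 0.107) and another of TNFAIP6 3.18 (adjusted p = 0.0598). A fit of theca arrays alone called 0 probe sets with limma, and 1986 had an unadjusted p under 0.05 in it, against 1765 over all arrays.

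Other key genes of large against small theca did not pass. LHCGR gave 1.48 (adjusted p = 0.208), HSD3B1 1.33 (adjusted p = 0.277), FST 1.36 (adjusted p = 0.363) and INHA 1.16 (adjusted p = 0.368). HSD17B1 gave -1.54, AMH -1.02, CYP11A1 0.83, STAR 0.67, CYP17A1 0.48, INSL3 -0.26 and FSHR 0.03. Of 16 granulosa markers 3 rose in theca (CYP19A1, INHBA and LOC767968), and 8 up and 1 down when adjusted over the list alone, the latter KRT18 (-1.36), with a median of 0.94 (adjusted p = 4.8e-05, and adjusted p = 0.443 with an estimated correlation).

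Endothelial markers were lower in large than in small theca for 12 of 14 genes, 4 when adjusted over the list alone (median -0.90, adjusted p = 3.62e-06, and adjusted p = 0.43 with an estimated correlation), with ROBO4 at -2.20 and CLDN5 at -1.40. Antioxidant genes were higher for 19 of 24 (median 0.50, adjusted p = 8.27e-05, and adjusted p = 0.384 with an estimated correlation), and hypoxia and glycolysis genes for 21 of 24 (median 0.47, adjusted p = 0.000183, and adjusted p = 0.459 with an estimated correlation). The 17 steroidogenesis genes shifted up, 1 called and 3 when adjusted over the list alone (median 0.52, adjusted p = 0.00142, and adjusted p = 0.265 with an estimated correlation; 0.0957 without theca small replicate 2). TGF-beta genes did so too (median 0.39, adjusted p = 0.00575, and adjusted p = 0.464 with an estimated correlation; 0.346 without theca small replicate 1, and lost without theca large replicate 2). Immune markers had a median of 0.59 (adjusted p = 0.0112, and adjusted p = 0.726 with an estimated correlation; 0.494 without theca large replicate 1, and lost without theca small replicate 2). Cholesterol genes had a median of 0.42 (adjusted p = 0.0119, and adjusted p = 0.7 with an estimated correlation). Cell cycle genes had a median of -0.19 (adjusted p = 0.0417, and adjusted p = 0.788 with an estimated correlation). Without theca small replicate 2 these lists had medians of 0.05 and 0.28 and tests that pointed the other way, and both calls were lost without theca large replicate 1, that of the cell cycle also without theca large replicate 2 and with log2(signal + 1) (adjusted p = 0.055).

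Between medium and small theca MFAP5, a protein of elastic microfibrils, rose 7.53-fold (2.91 ± 0.36, adjusted p = 0.0235), and the unnamed probe set that rose in large theca 14.4-fold (3.85 ± 0.53, adjusted p = 0.0393). These 2 were the probe sets called, among 1069 with an unadjusted p under 0.05. INHBA gave 3.31 ± 0.50 (adjusted p = 0.0636) and CYP19A1 3.08 ± 0.63 (adjusted p = 0.464). The limma count was 0 without theca medium replicate 1, where MFAP5 had an adjusted p of 0.64, 0 with a replicate block within each cell type, an alternative chosen after seeing the data (0.0728), and 0 without theca small replicate 1 or either small granulosa array, as well as without both arrays that stand apart. It was 1 without any of the 4 other granulosa arrays, 4 without theca medium replicate 2 or either large theca array, and 247 without theca small replicate 2. Cell cycle genes were higher for 26 of 29 members (median 0.46, adjusted p = 2.45e-05, and adjusted p = 0.603 with an estimated correlation; 0.88 without theca small replicate 1, and lost without theca medium replicate 2). Hypoxia and glycolysis genes were higher for 20 of 24 (median 0.37, adjusted p = 0.000521, and adjusted p = 0.464 with an estimated correlation; 0.0538 without both arrays that stand apart). Granulosa markers (median 0.42, adjusted p = 0.00678, and adjusted p = 0.573 with an estimated correlation; 0.419 without theca small replicate 1) and TGF-beta genes (median 0.40, adjusted p = 0.00707, and adjusted p = 0.464 with an estimated correlation; 0.687 without theca small replicate 1) shifted up, and neither was called without theca medium replicate 1. LH surge genes shifted down (median -0.36, adjusted p = 0.0385, and adjusted p = 0.464 with an estimated correlation; 0.227 without theca small replicate 1, and lost without theca small replicate 2 or theca medium replicate 2). Their call was also lost with log2(signal + 64) (adjusted p = 0.0627), without a filter (0.0759), with a filter at the 60th percentile (0.233) and after quantile normalization (0.0581). Cholesterol genes did likewise (median -0.36, adjusted p = 0.0485, and adjusted p = 0.765 with an estimated correlation), but turned to a median of 0.38 without theca small replicate 1 and were not called without theca medium replicate 1 or any of the 4 small and large granulosa arrays. Their call was lost with log2(signal + 1) (adjusted p = 0.0709), without a filter (0.074), with only the arrays compared (0.0705) and with the replicate number as a block (0.053).

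From medium to large follicles no single theca gene passed, and list shifts passed with the preset correlation only. With limma 0 probe sets were called and 539 had an unadjusted p under 0.05, below the 862 of chance. There was 1 call without theca medium replicate 1 or theca large replicate 1, and 0 without both arrays that stand apart. All 14 endothelial markers were lower in large theca, 9 of them when adjusted over the list alone (median -1.08, adjusted p = 4.56e-16, and adjusted p = 0.265 with an estimated correlation), with ROBO4 at -1.71 and CDH5, the cadherin of vessel junctions, at -1.40. All 29 cell cycle genes were lower, 0 of them called when adjusted over the list alone (median -0.75, adjusted p = 1.67e-15, and adjusted p = 0.368 with an estimated correlation), led by AURKB (-1.24) and CDC20 (-1.20). Cholesterol synthesis and uptake genes were higher for 15 of 17, 2 when adjusted over the list alone, TM7SF2 (2.05) and MSMO1 (1.44), at a median of 0.88 (adjusted p = 1.53e-09, and adjusted p = 0.437 with an estimated correlation). Of the key genes CYP19A1 gave 2.63 (adjusted p = 0.679), STAR 1.19, LHCGR 1.15 and HSD17B1 -1.92.

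Weaker shifts from medium to large theca were upward for immune markers (median 0.50, adjusted p = 5.76e-05, and adjusted p = 0.606 with an estimated correlation; 0.206 without theca large replicate 1) and granulosa markers (median 0.41, adjusted p = 0.000598, and adjusted p = 0.487 with an estimated correlation; 0.258 without theca medium replicate 2, and lost without theca large replicate 2). They were upward as well for LH surge genes (median 0.37, adjusted p = 0.00114, and adjusted p = 0.283 with an estimated correlation; 0.0846 without theca large replicate 1), steroidogenesis genes (median 0.24, adjusted p = 0.00315, and adjusted p = 0.274 with an estimated correlation) and antioxidant genes (median 0.24, adjusted p = 0.00346, and adjusted p = 0.487 with an estimated correlation; 0.0642 without theca large replicate 1). Downward shifts were seen for extracellular matrix genes (median -0.32, adjusted p = 0.00353, and adjusted p = 0.611 with an estimated correlation; 0.0839 without theca large replicate 2), WNT and NOTCH genes (median -0.35, adjusted p = 0.00578, and adjusted p = 0.274 with an estimated correlation; 0.0721 without theca medium replicate 1) and IGF system genes (median -0.36, adjusted p = 0.0372, and adjusted p = 0.346 with an estimated correlation; 0.214 without theca medium replicate 1, and lost without either large theca or either medium granulosa array, with log2(signal + 1), 0.0772, with a filter at the 60th percentile, 0.0698, and with only the arrays compared, 0.082).

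**Figure D3:**
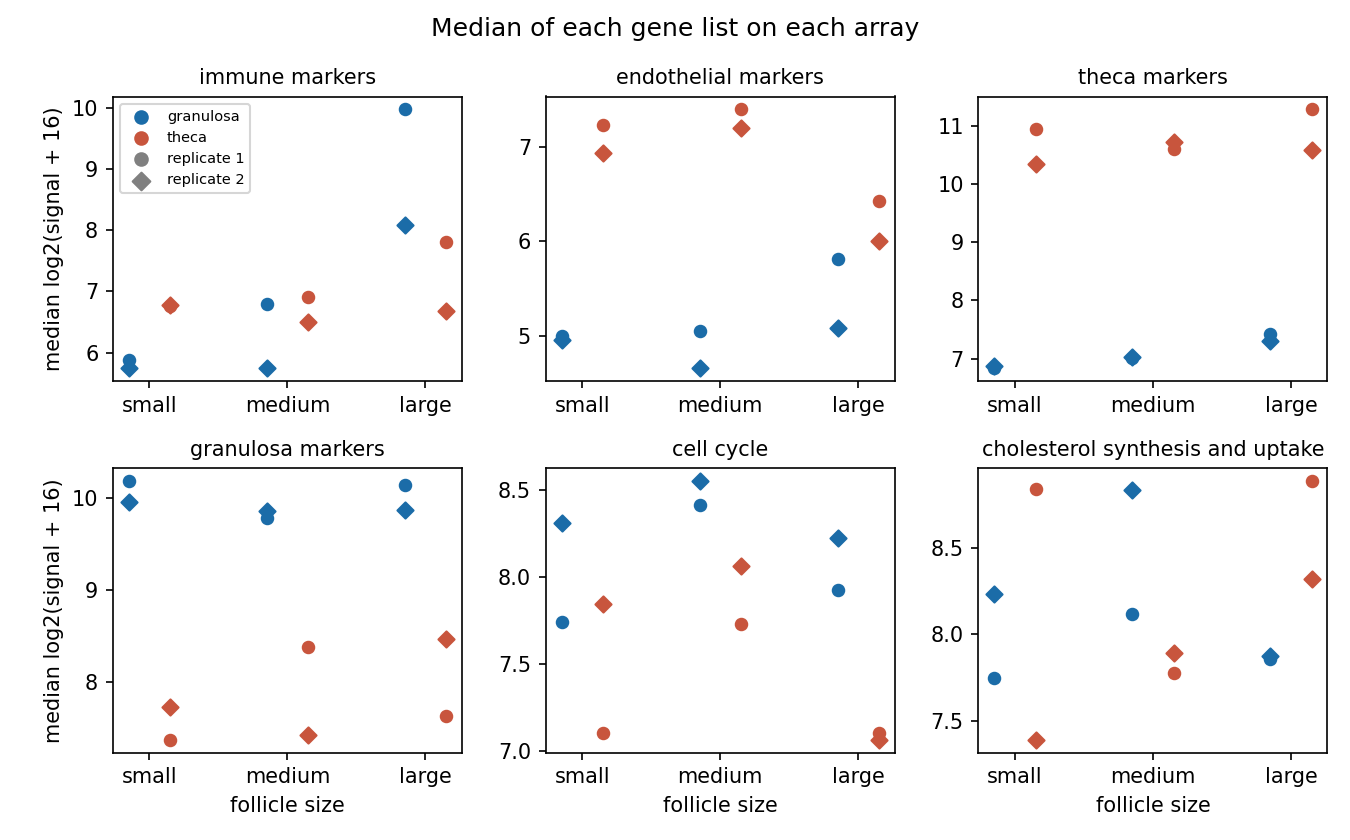
Median log2(signal + 16) of 6 gene lists on each of the 12 arrays, by cell type and follicle size, with circles for replicate 1 and diamonds for replicate 2. Immune markers stood at 9.98 and 8.10 in large granulosa and at no more than 6.80 in the small and medium granulosa arrays.

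Whether a size change differed between the layers was tested directly. CCL5 changed more in granulosa than in theca from small to large follicles, by 4.78 ± 0.62 (adjusted p = 0.036), and so did UCP2, a mitochondrial carrier (3.79 ± 0.53, adjusted p = 0.0419). From medium to large follicles the differences were 4.07 ± 0.57 for IGHM and 3.92 ± 0.53 for UCP2 (adjusted p = 0.0336 for each), 3.45 ± 0.51 for IGF2 (adjusted p = 0.0446) and 4.01 ± 0.57 for a probe set with no gene name here. UCP2 signals went from 1.7 and 10.2 in small to 214 and 94.7 in large granulosa, and from 105.5 and 83.3 to 45.5 and 39.9 in theca. The IGF2 probe set called here was not the gene's brightest. The brightest, which stood for IGF2 between the layers, was not called in this difference. One other probe set of IGF2 gave -0.31. No probe sets were called beyond the 2 and 4 given above. With limma 0 were called for medium against small, where 433 had an unadjusted p under 0.05. The large against small count was 268 without granulosa large replicate 2, 224 without theca small replicate 2, 1 without either medium granulosa array and 0 without any of the others, with an adjusted p of 0.397 for CCL5 and 0.448 for UCP2 without granulosa small replicate 1. The large against medium count was 67 without granulosa large replicate 2, 4 without either small theca array, 2 without granulosa medium replicate 1 and 0 without any of the others. Without theca small replicate 2 the medium against small count was 1. Without both arrays that stand apart the counts were 0 for large against small, 0 for medium against small and 1 for large against medium. A replicate block within each cell type, chosen after seeing the data, left 1 call for large against small, where UCP2 had an adjusted p of 0.0561, and 0 for large against medium (0.0702 for IGHM and IGF2, 0.0745 for UCP2).

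Across 17236 probe sets the large minus small changes of granulosa and theca correlated with Pearson's r = 0.186 and Spearman's rho = 0.149. These coefficients are across probe sets, which are not independent replicates, and the comparisons share no array. Of the 6 probe sets called up in theca, 3 were called up in granulosa, against 0.109 for independent lists. Both comparisons took the spread of a probe set from the same fit. The lists were therefore not independent, and 0.109 is not a chance level. Pearson's r was 0.0937 without granulosa large replicate 2.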

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

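The tests of leukocytes in granulosa samples and of granulosa cells in theca samples were written down before their values were seen. The tests of theca tissue in granulosa samples, of blood in each large granulosa array, of degraded RNA and of other splits of the arrays were chosen only after related results had been seen. The test of theca tissue replaced an earlier comparison of immune genes between the layers of large follicles, which had left the question open (median difference 1.52, with 14 of 18 genes higher in both granulosa arrays), and the blood test was divided by replicate, and its bounds changed, after its values were known.

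The values in the next 4 paragraphs were singled out because a direct test found that a size change differed between the cell types. Each is the change in granulosa minus the change in theca.

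Single genes differed as follows. For large against small follicles the difference was 4.78 for CCL5 (adjusted p = 0.036) and 3.79 for UCP2 (adjusted p = 0.0419). For large against medium follicles it was 4.07 for IGHM (adjusted p = 0.0336), 3.92 for UCP2 (adjusted p = 0.0336), 3.45 for IGF2 (adjusted p = 0.0446) and 4.01 for a probe set with no gene name here (adjusted p = 0.0336). The brightest probe set of IGF2 was not among the calls. The arrays whose omission ended these calls are named with the comparison itself.

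Among gene lists, 17 differences passed with the preset correlation and 0 with an estimated correlation (adjusted p = 0.274 to 0.679), and 6 of the 17 passed whichever single array was left out. Those were immune markers (2.91 for large against small, adjusted p = 5.5e-19, and 2.21 for large against medium, adjusted p = 2.75e-15), endothelial markers (1.45 for large against small, adjusted p = 5.8e-08, and 1.89 for large against medium, adjusted p = 1.11e-13), cholesterol genes (-1.17 for large against medium, adjusted p = 4.88e-07) and granulosa markers (-0.99 for large against small, adjusted p = 4.84e-05).

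Other list differences for large against small and large against medium follicles depended on single arrays. Granulosa markers for large against medium gave -0.76 (adjusted p = 0.1 without granulosa large replicate 2 and 0.0643 without theca medium replicate 2). Interferon genes for large against small gave 1.002 (adjusted p = 0.206 without theca large replicate 2 and 0.118 without granulosa large replicate 1). Antioxidant genes gave -0.48 (adjusted p = 0.176 without granulosa large replicate 2, 0.104 without theca small replicate 1 and 0.0981 without granulosa small replicate 2). For large against medium, fibroblast and stroma markers gave 0.69, extracellular matrix genes 0.69 and matrix proteases 0.80, and none was called without granulosa medium replicate 2. These differences rested on that array. Its median signals (log2) for the lists were 6.31, 6.74 and 6.48 in turn, against 7.57, 8.34 and 8.05 on granulosa medium replicate 1. The fibroblast list was not called without granulosa large replicate 2 or theca large replicate 1 either, nor the proteases without theca medium replicate 1.

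For medium against small follicles the differences were 0.62 for immune markers (adjusted p = 0.438 without granulosa medium replicate 1, 0.073 without theca medium replicate 2 and 0.0672 without granulosa small replicate 1). Cholesterol genes gave 0.70 (adjusted p = 0.419 without theca small replicate 1, 0.0936 without granulosa medium replicate 2 and 0.0558 without granulosa small replicate 1). The differences were -0.23 for hypoxia and glycolysis genes (adjusted p = 0.531 without granulosa small replicate 2, and not called without any other array but granulosa small replicate 1, theca small replicate 2 and theca medium replicate 2, nor with log2(signal + 1), 0.0624, a filter at the 60th percentile, 0.0556, or quantile normalization, 0.167) and -0.28 for antioxidant genes (adjusted p = 0.652 without theca small replicate 1, 0.431 without granulosa medium replicate 1, 0.251 without granulosa small replicate 2, 0.0664 without theca medium replicate 2 and 0.0576 after quantile normalization). Immediate early and heat shock genes gave -0.47 (adjusted p = 0.219 without granulosa small replicate 1, 0.183 without granulosa medium replicate 2, 0.127 without theca medium replicate 1 and 0.114 without theca small replicate 2).

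For the rise of immune genes in large granulosa, theca tissue carried into the samples is argued against as the whole cause. On the group means all 18 immune genes would have needed over 100% theca. The expected rises were therefore set at a share of 100%, that of samples made of theca alone. At that share 396 probe sets at least 4-fold higher in medium theca would have risen by a median of 2.19. They rose by 0.446 (quartiles -0.0955 to 0.993), and 376 of them lay below their own expected rise. That shortfall shows only that the samples were not theca alone, and does not bear on smaller shares. Blood stays open in both large arrays, since HBB stood at 9.22 in replicate 1 and 6.05 in replicate 2, above the 4.58 to 5.66 of the small and medium arrays. The rise of blood granulocyte and monocyte genes minus that of resident macrophage genes was -1.54 in replicate 1 (3.39 and 4.94) and 0.642 in replicate 2 (3.37 and 2.73), which decides nothing, as the signs differ and these genes are among the largest rises of the pattern. Leukocytes among the granulosa cells are a candidate source. Of 16 T cell genes outside the lists 9 could be tested, and these rose by a median of 1.71. Among them 5 were called, such as CD8A (2.52), CD8B (2.43) and CD3D (2.34). All 9 were higher in both large arrays than in the small and medium granulosa arrays. A gene dim elsewhere could pass the filter through large granulosa alone, and these genes may vary together. No chance level is therefore set against the 9. Whether leukocytes came with follicle size, which the design names, or with dissection was not tested, and the labels name no sorting step that would remove them.

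The rise of CYP19A1 and INHBA in large theca was weighed next. Granulosa cells in the large theca samples were considered first. On the group means CYP19A1 would have needed 111% granulosa RNA. Its signals overlapped, though, at 1633 and 4279 in large theca and 3134 and 1821 in large granulosa. The excess over 100% therefore does not decide whether granulosa cells were the whole cause. The expected rises were set at a share of 100%, that of samples made of granulosa alone. INHBA rose by 4.54, against 4.57 expected at a share of 100%. At that share 97 probe sets at least 4-fold higher in medium granulosa would have risen by a median of 1.96. They rose by 0.378 (quartiles -0.233 to 0.995), and 93 of them lay below their own expected rise. That shortfall shows only that the samples were not granulosa alone, and does not bear on smaller shares. Granulosa genes outside the pattern were set against the rise at a share of 100%. KRT18 (-1.36 against 2.17), HSD17B1 (-1.54 against 1.32), CDH2 (-0.36 against 1.81), FSHR (0.03 against 1.40), GATM (-0.07 against 1.16) and NR5A2 (1.61 against 3.31) lay far below it. SERPINE2 (0.73 against 0.84), FST (1.36 against 1.71) and INHA (1.16 against 1.70) did less so. Granulosa cells as a part of the cause were not tested. The median of the granulosa markers (log2) was 8.38 and 7.42 in medium theca and 7.625 and 8.46 in large theca. CYP19A1 signals differed in the same direction, at 912 and 184 and at 1633 and 4279. A share of granulosa cells that varied between theca samples thus stays open. Degraded RNA on theca small replicate 1 is argued against as the cause, because CYP19A1 rose by 5.27 without that array (adjusted p = 0.0418). A rise within theca cells with follicle size may be put forward as a hypothesis only, since it was found and examined on the same arrays and its calls were lost without theca large replicate 2 (CYP19A1 adjusted p = 0.0618, and 0.187 in a fit of theca arrays alone, the highest over its alternatives).

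Theca small replicate 1 stood apart from its replicate. Degraded RNA is a candidate cause: of 6 control transcripts with probe sets at both ends, 4 had their highest 3' over 5' ratio of the 12 arrays on this array. The ratios were 8.36 for GAPDH, 3.59 for cyclophilin, 102 for eIF-4E and 3.52 for GST, while actin was higher on granulosa large replicate 1 (21.0) than here. EF1A stood at 0.202 here, below the 0.221 of theca large replicate 2. The ratios of GAPDH, cyclophilin, actin and EF1A had been seen before the test was written. Only those of eIF-4E and GST had not. No biological explanation was tested for a difference within 1 group.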

How the results depend on the processing

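The omission of both arrays that stand apart, the crossed replicate block and the replicate block within each cell type were chosen only after the results had been seen, and the other alternatives beforehand. For every change given in this part the cause was not tested, although a fit with fewer arrays also has fewer degrees of freedom by construction. Directions were in large part fixed in advance. Leaving out an array outside a contrast leaves its log2 change as it was. Genes named as the largest rises or falls also had arrays that did not overlap. A kept direction is therefore no sign of a stable result. Of the named gene results with 1 array left out, 2600 kept direction and call, 211 lost the call, 11 gained one and 46 uncalled ones changed sign. Of the list results, 1142 kept both, 115 kept the direction but lost the call, and in 3 the test turned direction. The 3 are not counted among the lost calls. Direction here is that of the list test, and the median of a list could turn without it. List calls were lost for 7 with log2(signal + 1), 3 with log2(signal + 64), 3 without filter and 7 with the filter at the 60th percentile. They were lost for 4 with quantile normalization, 2 with only the arrays compared, 1 with the replicate block and 17 without both arrays that stand apart. These are out of the calls each could test. Without both arrays the test of 1 further list turned direction. Among named genes the call was lost for 39 with log2(signal + 1), 21 with log2(signal + 64), 18 without filter, 6 with quantile normalization, 12 with only the arrays compared, 1 with the replicate block and 44 without both arrays that stand apart. In simulated data for large against small granulosa, 5.97% of probe sets with a log2 change of 1 were recovered, 83.6% at 2 and 100% at 3. Those data held independent values and the same spread in all groups, so the rates need not hold for the real arrays. How far signals near the background limit the calls was tested only through the added constants and filters. Quantile normalization moved the median of all probe sets in the large cell type comparison from 0.124 to 0.00184 and in the large against small difference between cell types from 0.0661 to -0.0586, so changes there are relative to such shifts.

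Counts of called probe sets moved by over 1.5 times as follows. With log2(signal + 1) there were 227 in large against small granulosa, 0 in medium against small granulosa, 5 in large against medium granulosa, 0 in medium against small theca and 367 between cell types in large follicles. The differences between cell types in large against small and large against medium were then 0 and 0, and the correlation of the large minus small changes was 0.14. With log2(signal + 64) the counts were 158 and 26 for large against small and large against medium granulosa, 1 for medium against small theca, and 0 and 0 for those differences between cell types. Without the filter they were 0 for medium against small granulosa, 38 for large against medium granulosa, 0 for medium against small theca, and 0 and 0 for the differences. With the filter at the 60th percentile they were 0 for medium against small granulosa and 1 for medium against small theca, with a correlation of 0.225. Quantile normalization gave 1 for medium against small theca and 0 for the large against small difference, and the trended prior 0 for medium against small granulosa. With only the arrays compared the counts were 3 for medium against small granulosa, 0 for large against small theca, 0 for medium against small theca, 925 between cell types in small follicles and 367 in large ones.

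The labels do not say what a replicate number shares. Deviations of same-numbered arrays correlated above 0 within a cell type (0.0727 to 0.402 in granulosa, 0.14 to 0.267 in theca) and between -0.335 and 0.142 across cell types, over 0.1 in 6 of 15 pairs of groups. These correlations show no common pairing over all groups but cannot exclude one, since the arrays that stand apart enter them. A pairing within theca, where all 3 pairs of groups exceeded 0.1, and within granulosa stays open. With the replicate block the counts were 0 for medium against small granulosa, 213 for large against medium granulosa, 1 for medium against small theca, 1 for large against medium theca and 1 for the large against small difference. The block moved no other count by over 1.5 times, and of the named calls it ended those of UCP2 in the large against small difference (adjusted p = 0.0538) and of the cholesterol list in medium against small theca (0.053). With the numbers crossed, 2229 probe sets differed between cell types in small follicles and 1299 in medium ones. With a replicate block within each cell type the counts were 0 for medium against small granulosa, 236 for large against medium granulosa, 0 for medium against small theca, 2418 and 1286 between cell types in small and large follicles, and 1 and 0 for the large against small and large against medium differences. That block ended 7 named gene calls and 4 list calls and added 1, of LHCGR in large against small granulosa (adjusted p = 0.0462).

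Without both arrays that stand apart the counts were 58, 12 and 0 for large against small, medium against small and large against medium granulosa, 1 and 0 for large against small and medium against small theca, 797 and 1600 between cell types in small and medium follicles, and 0 and 1 for the large against small and large against medium differences. The correlation was 0.268, and the cholesterol list of medium against small theca turned to 0.38. With an estimated correlation 4 list tests passed.

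Other probe sets of 2 genes pointed the other way. For MGP between cell types they gave 0.22 over all sizes, 0.33 and 0.084 in medium and 0.32 in large follicles. For IGF2 they gave 0.38 over all sizes, 0.86 in medium follicles and -0.31 in the large against medium difference.

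With single arrays left out, counts ranged from 0 to 635 for large against small granulosa, 0 to 8 for medium against small, 0 to 487 for large against medium, 0 to 607 for large against small theca, 0 to 247 for medium against small and 0 to 1 for large against medium. Between cell types they ranged from 2648 to 4844 over all sizes, 501 to 2232 in small, 360 to 1301 in medium and 199 to 1013 in large follicles. The differences ranged from 0 to 268 for large against small, 0 to 1 for medium against small and 0 to 67 for large against medium, and the correlation from 0.0937 (without granulosa large replicate 2) to 0.259 (without granulosa large replicate 1). The highest counts between cell types came without theca small replicate 2, in medium and large follicles without either small theca array. The arrays behind the other ends are named with each comparison. Cholesterol genes ranged from 0.046 (test reversed without theca small replicate 2) to 1.21 in large against small theca and from -0.92 to 0.38 (without theca small replicate 1) in medium against small theca, and cell cycle genes from -0.66 to 0.28 (without theca small replicate 2) in large against small theca.

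Where limma made 0 calls under an alternative, the probe sets with an unadjusted p under 0.05 numbered 1780 for large against small, 395 to 892 for medium against small and 1021 to 1717 for large against medium granulosa. In theca they were 817 to 1986, 388 to 1626 and 266 to 894 in the same order, and for the differences between cell types 1135 to 2386, 215 to 839 and 699 to 1736.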

Other observations

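The genes in the next paragraph were singled out after their values had been seen, and the test of other splits was written after the result it bears on.

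Large granulosa differed from small granulosa in further members of the lists. OXT, which encodes oxytocin and is a hormone gene of the maturing follicle and corpus luteum, rose by 2.49 (adjusted p = 0.0219), and TNC, a matrix protein of remodelling tissue, by 2.10 (adjusted p = 0.00827). The insulin receptor INSR (-1.81, adjusted p = 0.0413), STC1, a secreted glycoprotein (-1.79, adjusted p = 0.0392), and APOD (-2.05, adjusted p = 0.0144) fell. Other probe sets of INSR gave -1.89, -0.98 and -0.37, and others of APOD -1.63 and -1.15, of which only the -1.89 passed. With limma no call at all was made in this comparison without granulosa large replicate 1, and 2 were made without granulosa small replicate 1.

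Among 100 splits of the 12 arrays into 6 and 6, drawn from 462 and with the real one included, 1 called as many probe sets as granulosa against theca. The real split called 4195 in a fit of 2 groups that also held follicle size, and the highest of the others called 539. A share of 1 in 100 is the lowest that 100 splits can give. All other splits mixed the cell types, so their fits held the difference between the layers as spread, which lowers their counts. The difference had also been seen before the test was written. The test therefore cannot decide on chance and adds no support of its own.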
